A study of Mus musculus with 12 samples.

How the data were processed

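Polyadenylated RNA of mouse liver, freeze-clamped at collection, was sequenced in 12 libraries, 6 from control livers (WT) and 6 from livers with hepatocyte deletion of Acly and Acss2 (DKO). Groups were taken from the genotype label of each sample. The deposited table holds log2 CPM (read counts scaled to library size), filtered and normalized between libraries by the authors, per the name of the file; the filter, the added count and the normalization factors are not given in the sources used here. The submitters' processing notes name kallisto 0.46.2, edgeR and limma and the mouse genome build GRCm39 (mm39), with no role for any of them. The table had 12285 rows, of which 1 had no name; it held 0.0075% to 0.0148% of the CPM of a library and was left out. Gene symbols were used as deposited. Of the symbols 20 had been turned into calendar dates and 2 occurred more than once; these rows were tested but not named. The reference at hand was of another build, so no coordinates were given.

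The values had a shared lowest value of -3.26 log2 CPM (0.104 CPM), at which 25 to 61 genes stood per library. Back-transformed values summed to between 906047 and 1088120 CPM per library and the 10 most abundant genes took 17.8% to 21.9%. Every gene exceeded 1 CPM in at least 1 library. Whole reads could not be recovered from log2 values with an added count, and the depth of each library is unknown; precision was therefore judged from the spread between libraries alone. Libraries of one group correlated with their group at a mean Pearson r of 0.945 to 0.965 across genes, and none was a duplicate of another.

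Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the mean trend, 2-sided) on the deposited log2 CPM of all 12 libraries, without a filter, a covariate or a further pseudocount, and p-values were adjusted by the Benjamini-Hochberg method over 12284 genes. A gene was called at an adjusted p below 0.05. "Rose" and "fell" are used for called genes, and "over the list alone" means adjustment over the members of 1 list. Single values were compared by 2-sided exact permutation tests over all divisions of the libraries into 6 and 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

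The 40 gene lists, fixed before the data were examined, held neither Acly nor Acss2. The 10 primary lists were fatty acid synthesis with SREBP1c or ChREBP targets, polyunsaturated fatty acid synthesis, cholesterol synthesis with SREBP2 targets, LXR targets with cholesterol export, mitochondrial fatty acid oxidation with ketogenesis, PPARα targets, lipid droplet and triglyceride storage, other acetyl-CoA enzymes with citrate transport, extracellular matrix and fibrosis, and macrophages and monocytes. The 30 secondary lists covered sugar, bile acid and lipoprotein metabolism, hepatocyte identity and zonation, other cell types of liver and neighbouring tissues, stress and transcription factor programmes, the cell cycle, the clock, sex-biased genes, hormone signalling, mitochondrial, ribosomal, acute phase, interferon and immediate early genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes. The mean log2 CPM of each list per library was compared by the exact permutation test, adjusted over the 10 cell type lists as planned. Its adjustment over all 40 lists was added after seeing that other divisions of the libraries gave many camera calls.

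The named genes followed a rule fixed at the same time. It took Acly and Acss2, and the 6 largest changes in each direction among called genes with a mean of at least 1 log2 CPM, no overlap of the groups and an established symbol. It also took the 2 called members with the largest change in each direction of each primary list and the 1 such member of each secondary list, or the member with the smallest p where none was called. A fixed set was named whatever its result: Srebf1, Mlxipl, Fasn, Cyp7a1, Ppara, Cpt1a, Fgf21, Pparg, Cd36, Acss1 and Col1a1. Some genes of the rule are not reported here, which left 66 with values, and genes named beyond it are marked where they appear.

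The same fit was tested on simulated data for 6 against 6 libraries and 12284 genes. It recovered 31.3% of 67 genes changed by 0.5 on the log2 scale, 73.1% of 67 changed by 1 and 90.9% of 66 changed by 2, with 5 false calls among 135. A list of 24 genes shifted by 0.5 was found, with 0 of the 39 other lists called. Genes were simulated as independent of each other. The simulation therefore does not show how often false calls arise where genes vary together, for camera's lists above all. Alternatives were limma without the mean trend, robust limma, log2(CPM + 1), filters at a mean of 1 or 3 log2 CPM, subtraction of library medians, quantile normalization, array weights, the replicate number as a block, each library left out in turn and an exact rank-sum test. For marker levels the mean CPM relative to WT was the alternative.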

Results

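Hepatic gene expression was measured by sequencing of polyadenylated RNA in 12 mouse liver libraries, 6 from control livers (WT) and 6 from livers whose hepatocytes had lost both Acly and Acss2 (double knockout, DKO). Both groups carried floxed alleles of the 2 genes. A hepatocyte-directed adeno-associated virus delivered Cre recombinase to the DKO group and GFP to the WT group at 6 to 8 weeks of age. A Western diet, rich in fat, sugar and cholesterol, started 1 week later and was fed for 6 weeks. Values were log2 CPM, read counts scaled to library size, for 12284 named genes, and the back-transformed values summed to between 906047 and 1088120 CPM per library. The number of reads behind each library was unknown, so no counting interval could be given. The labels did not say that each library came from a separate mouse, so p-values measured the spread between libraries.

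The comparison of DKO with WT addressed what joint loss of these 2 sources of acetyl-CoA does in the liver during Western diet feeding. Effects of Cre or GFP themselves cannot be told apart from the loss, since the groups differed in both. Acly encodes ATP citrate lyase, which makes cytosolic acetyl-CoA from citrate, and its level fell from 7.61 ± 1.00 log2 CPM in WT to 5.10 ± 0.86 in DKO (SD, n = 6 each), 17.6% of the WT level. Acss2 encodes the synthetase that makes acetyl-CoA from acetate, and fell from 6.51 ± 0.48 to 4.33 ± 0.82 log2 CPM, 22% of the WT level. The log2 fold change was -2.51 (SE 0.46; limma adjusted p = 0.0165; exact permutation p = 0.00433) for Acly and -2.18 (SE 0.33; limma adjusted p = 0.00571; exact permutation p = 0.00216) for Acss2. The second exact p is the smallest that the divisions of 12 libraries into 6 and 6 allow. All 6 DKO libraries lay below the WT mean of both genes. Acss2 did not overlap between the groups, and for Acly the library DKO 1 (6.60 log2 CPM) lay above the lowest WT library, WT 5 (6.56). The values cover whole genes, and which exons were floxed is not given in the sources used here.

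**Figure D1:**
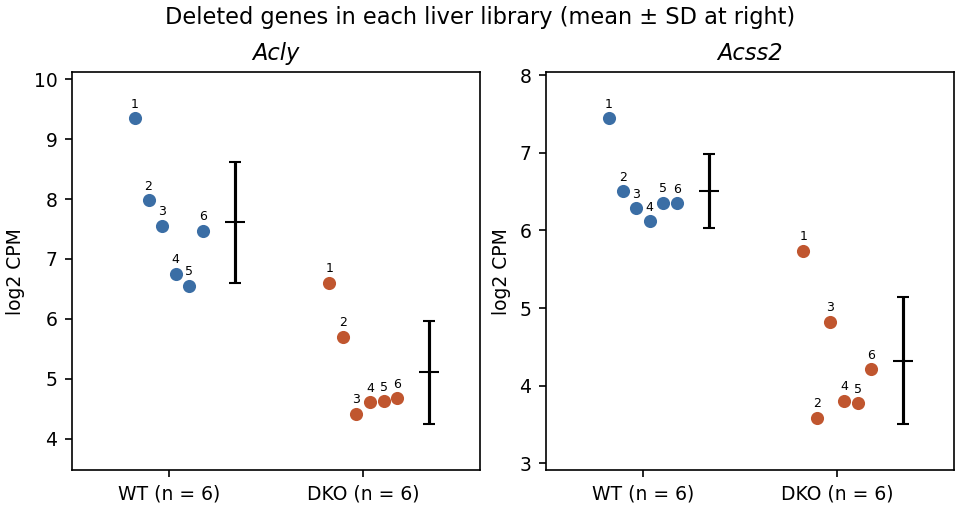
Acly (left) and Acss2 (right) in log2 CPM for each of the 6 WT and 6 DKO liver libraries (points, numbered by replicate), with the mean ± SD at the right of each group. The DKO means were 5.10 for Acly and 4.33 for Acss2, against 7.61 and 6.51 in WT, and the library numbered 1 was the highest of its group for both genes.

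Across the liver transcriptome, 214 of 12284 genes (1.74%) changed between the groups, 76 higher and 138 lower in DKO, and 71 of them changed at least 2-fold (44 higher and 27 lower). Among called genes with a mean of at least 1 log2 CPM and separated groups, the largest rises were those of Gstm3, a glutathione S-transferase (6.64-fold, log2 fold change 2.73, SE 0.17, limma adjusted p = 3.34e-06), and Ighm, the heavy chain of IgM (4.66-fold, adjusted p = 0.0453). Next came Ephb2, a receptor tyrosine kinase for ephrins (4.41-fold, adjusted p = 0.000953), and Mmp12, the macrophage elastase (4.40-fold, adjusted p = 0.0148). Tmem86a, a lysoplasmalogenase, rose 3.06-fold and Btg3, an antiproliferative gene, 3.04-fold (adjusted p = 0.00104 and 0.00322). Under the same limits and besides Acss2, the largest falls were in Car14, a membrane carbonic anhydrase, which dropped to 25.6% of WT (log2 fold change -1.96, SE 0.22, adjusted p = 0.00078), and Adam11, at 28.7% (adjusted p = 0.0210). Sult5a1, a sulfotransferase, fell to 33.1% of WT, Lrtm1 to 33.6% and Ces4a, a carboxylesterase, to 38.0% (adjusted p = 0.0176, 0.0120 and 0.0376). The 6 WT and 6 DKO values did not overlap for 266 genes, 2.17% of those tested against 0.216% from chance, and 146 of the 214 called genes were among them.

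Genes were called with limma at an adjusted p below 0.05, and 2017 genes had an unadjusted p below 0.05 where 614.2 would be expected by chance. The number called depended on single libraries: it was 373 without WT 1, and 107, 112, 122, 92 and 102 without WT 2, WT 3, WT 4, WT 5 and WT 6, then 124, 107 and 93 without DKO 1, DKO 3 and DKO 4. An exact rank-sum test called 0 genes (1742 at an unadjusted p below 0.05), since a call would have needed 532 genes at the smallest p that 6 against 6 libraries can give and 266 had it. Of the 38 named genes that were called, 20 kept their call with any 1 library left out, among them Acly, Acss2, Gstm3, Ephb2, Mmp12, Tmem86a, Btg3, Car14, Sult5a1 and Lrtm1. Of the genes with the largest changes, Ighm (adjusted p up to 0.0998), Ces4a (up to 0.0893) and Adam11 (up to 0.0560) lost it without some single libraries. In DKO, Ighm spanned 2.87 to 7.01 log2 CPM, highest in DKO 1. It also lost its call with robust limma, log2(CPM + 1), quantile normalization or no mean trend. Gstm3 has near-identical paralogs, so its level may include shared reads.

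**Figure D2:**
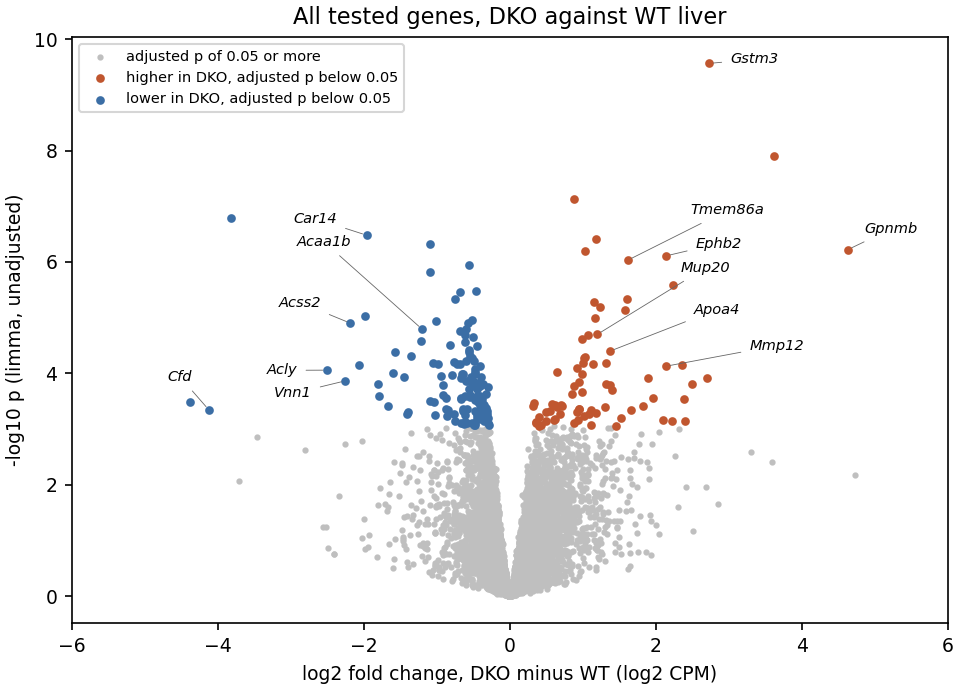
Log2 fold change of every tested gene (x axis, DKO minus WT, log2 CPM) against -log10 of the unadjusted limma p (y axis), with the 76 genes that rose in orange, the 138 that fell in blue and genes with an adjusted p of 0.05 or more in grey. Gstm3, Gpnmb, Ephb2 and Tmem86a stand at the upper right, Car14, Acss2 and Acly at the upper left.

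The mean level of mitochondrial fatty acid oxidation and ketogenesis genes was lower in the DKO liver. Of the 21 measured members of this list, 19 were lower in DKO, 7 fell and 0 rose, and 17 fell when adjusted over the list alone. Among those that fell were Acaa2, Acadvl, Acat1, Etfa and Etfb, named after their values were seen, of which Acaa2, the thiolase of mitochondrial oxidation, fell to 75.4% of WT (limma adjusted p = 0.0148). The mean level of the list was 8.29 ± 0.15 log2 CPM in WT and 7.97 ± 0.10 in DKO (SD, n = 6 each; exact permutation p = 0.00216; adjusted p = 0.0289 over the 40 lists), with a median log2 fold change of -0.33 and a camera adjusted p of 1.40e-13. The camera adjusted p was 0.20 with an estimated correlation, and the directional fry adjusted p was 0.0119. Leaving out 1 library, the list's adjusted exact p reached 0.0577 without DKO 1, DKO 3, DKO 4 or DKO 5. Cpt1a, the carnitine acyltransferase that admits fatty acids to mitochondria, differed by 0.02 on the log2 scale (SE 0.15, adjusted p = 0.975). Beside this list, the hepatocyte identity markers had a median log2 fold change of -0.16 in DKO.

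The list of PPARα targets, of peroxisomes, omega-oxidation and acyl-CoA hydrolysis, was lower in DKO for 24 of 27 measured genes; 5 fell, 0 rose, and 15 fell when adjusted over the list alone. Vnn1, a pantetheinase, fell from 5.57 ± 0.73 to 3.32 ± 1.00 log2 CPM (SD, n = 6 each; 21% of WT, limma adjusted p = 0.0200). Acaa1b, a peroxisomal thiolase, fell to 43.4% of WT (adjusted p = 0.00678), and Acaa1a, Ech1 and Eci2, named after their values were seen, also fell. The median log2 fold change was -0.67 with a camera adjusted p of 3.51e-11 and a fry adjusted p of 0.0322. The adjusted p was 0.20 with an estimated correlation and 0.0866 in the exact permutation test of the mean level (unadjusted exact p = 0.0238), so this call held by 2 of these tests; without WT 1 the adjusted exact p was 0.0289. Ppara itself had a log2 fold change of -0.18 (SE 0.14, adjusted p = 0.552) and Fgf21, a hormone it induces, 0.84 (SE 0.57, adjusted p = 0.502). Vnn1 lost its call without WT 3, WT 5 or DKO 4, with an adjusted p of up to 0.0524.

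Macrophage and monocyte markers had a higher mean level in DKO: all 24 measured markers were higher, 3 rose, and 20 rose when adjusted over the list alone. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from -2.40 ± 1.15 to 2.23 ± 0.83 log2 CPM (SD, n = 6 each; adjusted p = 0.000851); 3 libraries were at the lowest value of the table, so the size of this change depends on how low values were treated, and it was 2.23 on the log2(CPM + 1) scale. Ccr2, the chemokine receptor of recruited monocytes, rose 2.65-fold (adjusted p = 0.0244), and Lyz2, the macrophage lysozyme, named after its value was seen, rose 1.93-fold. The mean level of the markers was 3.10 ± 0.20 log2 CPM in WT and 4.003 ± 0.33 in DKO (exact permutation p = 0.00216; adjusted p = 0.0216 over the 10 cell type lists and 0.0289 over all 40 lists). The camera adjusted p was 6.22e-14, the fry adjusted p 0.0119, and the camera adjusted p 0.20 with an estimated correlation. Over the 40 lists the adjusted exact p was 0.0577 without WT 2, WT 3, WT 5 or WT 6 and 0.0519 without WT 4, and Ccr2 had an adjusted p of up to 0.0604 without WT 2, WT 3, DKO 3 or DKO 4.

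Extracellular matrix and fibrosis genes were higher in DKO for 25 of 28 measured members; 2 rose, and 14 rose when adjusted over the list alone. Spp1, osteopontin, rose 1.83-fold (from 4.26 ± 0.30 to 5.13 ± 0.35 log2 CPM, adjusted p = 0.0213), and Sparc, a matrix-binding glycoprotein, rose 1.42-fold (adjusted p = 0.0453). Col1a1, a chain of type I collagen, had a log2 fold change of 1.02 (SE 0.33), which did not pass (adjusted p = 0.130). The camera adjusted p of the list was 7.13e-09 and the fry adjusted p 0.0322, against 0.241 with an estimated correlation and 0.0866 in the exact permutation test of the mean level. Spp1 lost its call without WT 6 or DKO 1 (adjusted p up to 0.0560), and Sparc without any of 10 single libraries (up to 0.104).

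The other cell type lists moved less. All 20 endothelial markers were higher in DKO but 0 passed the test over all genes or over the list alone (limma; Cdh5, the closest, had an adjusted p of 0.120), while their mean level differed by 0.23 (exact permutation p = 0.00866, adjusted p = 0.0433 over the cell type lists and 0.0693 over all 40). Hepatocyte identity markers were lower for 21 of 26 genes, with Asgr1, a receptor for asialoglycoproteins, at 78.4% of WT (adjusted p = 0.0452), and a mean level that differed by -0.14 (adjusted exact p = 0.0649). Of 13 cholangiocyte markers, 1 rose, Cd24a (1.93-fold, adjusted p = 0.0357), and of 19 stellate cell and fibroblast markers, 15 measured dendritic cell and antigen presentation genes, 8 red blood cell genes, 8 lymphocyte genes and 6 neutrophil genes 0 were called. The members closest to the threshold were Rgs5 (adjusted p = 0.105), Cd74 (0.0902), Hba-a2 (0.241), Cd79b (0.369) and Mmp9 (0.103). The adjusted exact p of the mean level was 0.781 for cholangiocytes, 0.136 for stellate cells, 0.0823 for dendritic cells, 0.203 for red cells, 0.476 for lymphocytes and 0.0758 for neutrophils. Camera adjusted p were 9.67e-06 for endothelial cells (0.20 with an estimated correlation), 0.00289 for hepatocyte identity (0.283), 0.0174 for stellate cells (0.428) and 0.0165 for dendritic cells (0.479). Those of cholangiocytes, red cells, lymphocytes and neutrophils were 0.608, 0.0809, 0.529 and 0.171. Adjusted over the list alone, 1 hepatocyte marker rose and 3 fell, 1 cholangiocyte, 3 dendritic cell and 1 neutrophil gene rose, and 0 stellate, red cell or lymphocyte genes were called by limma. Camera's call was lost for stellate cells without WT 5 or DKO 2 (adjusted p up to 0.105) and for dendritic cells without DKO 4 (0.0806).

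Among 3 measured genes of the pancreas, adipose tissue and gallbladder, Cfd, the adipocyte protease adipsin, fell to 5.73% of WT (adjusted p = 0.0364, with 2 libraries at the lowest value of the table). For that list the median log2 fold change was 0.48 and the mean -0.83, with camera's direction up (adjusted p = 0.678) and an exact permutation p of 0.0866 adjusted over the cell type lists; 1 gene rose and 1 fell when adjusted over the list alone. The calls of Asgr1, Cd24a and Cfd were lost without 10, 8 and 10 of the single libraries, with adjusted p of up to 0.105, 0.0858 and 0.0850.

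NRF2 targets and glutathione genes had a higher mean level in DKO; 19 of 24 were higher, 5 rose and 0 fell, with 8 rising and 1 falling when adjusted over the list alone. Besides Gstm3, those that rose were Gsta1, Gstm2, Gstm1 and Srxn1, the sulfiredoxin, named after their values were seen; Gstm1 rose 2.05-fold and Gstm2 2.26-fold. The mean level of the list was 6.42 ± 0.06 log2 CPM in WT and 6.84 ± 0.15 in DKO (SD, n = 6 each; exact permutation p = 0.00216, adjusted p = 0.0289 over the 40 lists). The median log2 fold change was 0.17, the camera adjusted p 4.32e-05 and the fry adjusted p 0.0119, and the camera adjusted p was 0.20 with an estimated correlation. Reads of the Gstm genes may be shared between these close paralogs, and how they were assigned is not given in the sources used here. All genes of the list that rose, except Srxn1, were glutathione S-transferases, and the list's mean log2 fold change (0.42) exceeded its median. The list was not tested without the Gstm genes, so how far its call rests on them is unknown.

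**Figure D3:**
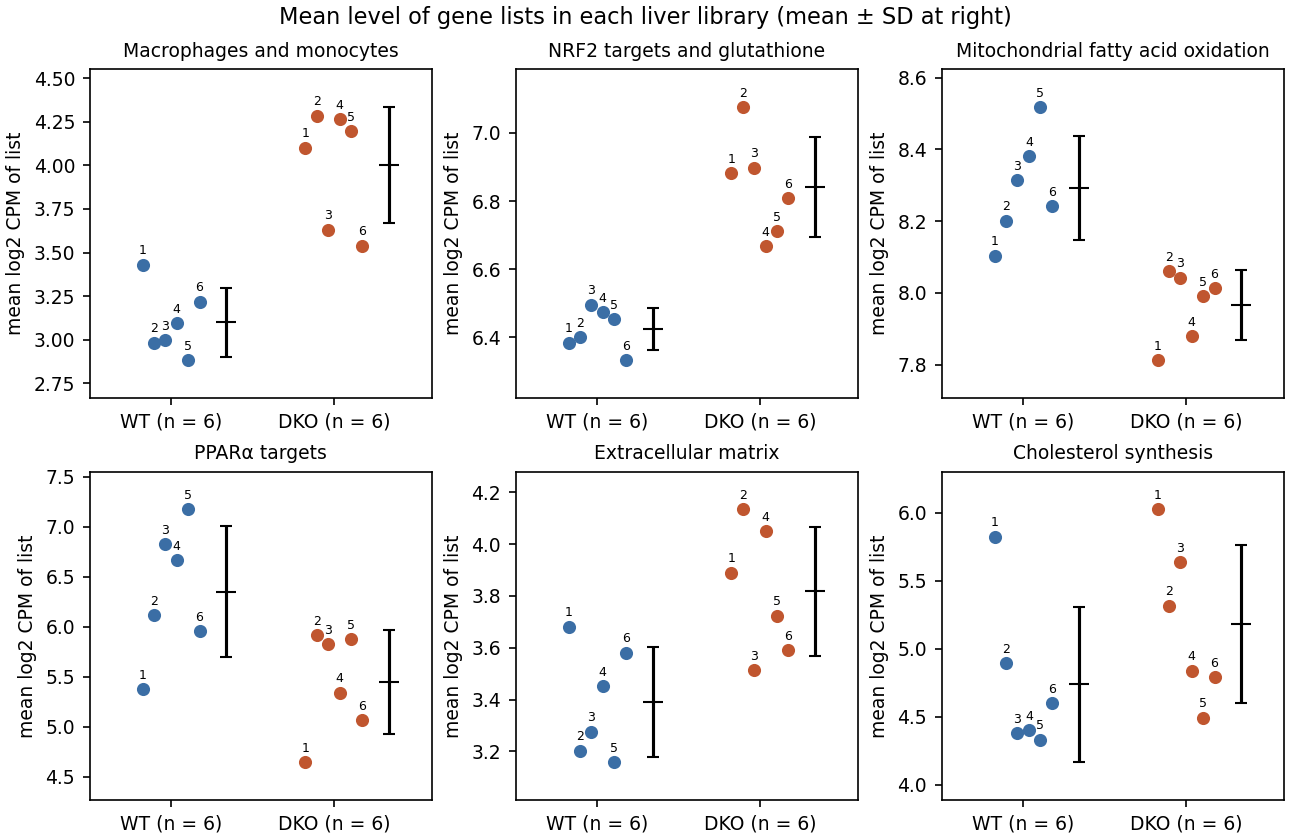
Mean log2 CPM over the measured members of 6 gene lists in each of the 6 WT and 6 DKO libraries (points, numbered by replicate), with the mean ± SD at the right of each group. The groups did not overlap for macrophages and monocytes, NRF2 targets and glutathione, or mitochondrial fatty acid oxidation, and overlapped for PPARα targets, extracellular matrix and cholesterol synthesis.

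The lists of fatty acid synthesis did not pass camera's threshold in the fit to all 12 libraries. Among 24 genes of fatty acid synthesis and of the SREBP1c and ChREBP programmes, 2 fell: Acss3, a mitochondrial acyl-CoA synthetase, to 54.7% of WT (adjusted p = 0.0286) and Agpat2, an acyltransferase of triglyceride and phospholipid synthesis, to 65.9% (adjusted p = 0.00678). Adjusted over the list alone, 3 fell and 0 rose. Fasn, fatty acid synthase, had a log2 fold change of 0.20 (SE 0.68, adjusted p = 0.923), Srebf1 -0.86 (SE 0.35, adjusted p = 0.230) and Mlxipl, the gene of ChREBP, -0.59 (SE 0.17, adjusted p = 0.0928). The list had a median log2 fold change of 0.08 and a mean of 0.02 while camera's direction was down (adjusted p = 0.608, and 0.892 with an estimated correlation). In polyunsaturated fatty acid synthesis, Hsd17b12, a reductase of chain elongation, fell to 73.4% of WT (adjusted p = 0.0103); 6 of 8 genes were higher, 3 rose and 1 fell when adjusted over the list alone. The camera adjusted p of that list was 0.0869, and below 0.05 without WT 1, DKO 5 or DKO 6 (lowest 0.0269). Acss3 lost its call without WT 3, WT 5, WT 6, DKO 3 or DKO 5 (adjusted p up to 0.0758).

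Cholesterol synthesis and SREBP2 target genes were higher in DKO for 21 of 25 members, but 0 were called by limma, over all genes or over the list alone. Ebp, a sterol isomerase, was closest, with a log2 fold change of -0.28 (SE 0.07, adjusted p = 0.0744). The median log2 fold change of the list was 0.32 with a camera adjusted p of 0.00406, which ended with an estimated correlation (adjusted p = 0.620), with fry (0.390), with the exact permutation test of the mean level (0.326) and with camera when DKO 1 was left out (0.0814). The 2 libraries numbered 1 had the highest mean levels of their groups, 5.83 log2 CPM in WT 1 and 6.03 in DKO 1, against group means of 4.74 ± 0.57 and 5.18 ± 0.58 (SD, n = 6 each). Among 10 LXR targets and cholesterol export genes 0 were called by limma; Lpcat3, a phospholipid acyltransferase, had a log2 fold change of -0.43 (SE 0.11, adjusted p = 0.0656). Adjusted over the list alone, 1 LXR target rose and 1 fell, and the list's camera adjusted p was 0.671.

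In lipid droplet and triglyceride storage, Plin3, a droplet coat protein, rose 1.34-fold (adjusted p = 0.0494) and Fitm1, a protein of droplet formation, fell to 48.0% of WT (adjusted p = 0.0144). Of 20 measured genes 15 were lower in DKO; adjusted over the list alone, 1 rose and 2 fell. Cd36, a fatty acid transporter, had a log2 fold change of 0.01 (SE 0.27, adjusted p = 0.992) and Pparg -0.77 (SE 0.36, adjusted p = 0.307). The camera adjusted p was 0.0143, 0.398 with an estimated correlation, 0.153 with fry and 0.181 in the exact permutation test of the mean level. Among 23 other enzymes of acetyl-CoA and citrate transport, Pcx, pyruvate carboxylase, fell to 64.0% of WT (adjusted p = 0.0177) and 17 genes were lower, 2 falling when adjusted over the list alone. That list had a camera adjusted p of 0.00373, 0.20 with an estimated correlation, 0.0213 with fry and 0.0649 in the exact permutation test. Acss1, the mitochondrial acetyl-CoA synthetase, was not analysed here. Plin3 lost its call without any of 10 single libraries (adjusted p up to 0.113), and the lipid droplet list lost its camera call without WT 3 (0.0575).

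Several other lists of hepatocyte metabolism were lower. The hepatocyte identity markers were lower as well (21 of 26, median log2 fold change -0.16, camera adjusted p = 0.00289). Medians were -0.25 for glycolysis, -0.18 for oxidative phosphorylation and -0.13 for bile acid genes. Whether they fell beyond the identity markers was not tested. Of 24 genes of glycolysis, gluconeogenesis and fructose metabolism, 21 were lower in DKO and 1 fell, Fbp1, fructose bisphosphatase, at 73.0% of WT (adjusted p = 0.0437); the list had a camera adjusted p of 1.64e-05 and a fry adjusted p of 0.0179. Of 35 nuclear genes of oxidative phosphorylation, 32 were lower and 1 fell (camera adjusted p = 3.54e-08, fry 0.0322). Of 26 bile acid genes 21 were lower, with Hsd17b4, a peroxisomal oxidation enzyme, at 76.2% (adjusted p = 0.0187; camera 0.00416, fry 0.0322), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.54 (SE 0.29, adjusted p = 0.372). Of 18 clock and clock output genes 17 were lower and 0 were called by limma (Tef, adjusted p = 0.177; camera 0.00289, fry 0.0441). With an estimated correlation these 4 lists had adjusted p of 0.20, 0.264, 0.20 and 0.20, and in the exact permutation test 0.124, 0.0866, 0.157 and 0.0866, so none passed there. Adjusted over the list alone, 5, 5, 1 and 0 of their genes fell. Fbp1 lost its call without 10 of the single libraries (adjusted p up to 0.0991). The labels give no time of collection, so for the clock list a difference in time of day between the groups cannot be told apart.

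Apoa4, an apolipoprotein of triglyceride-rich particles, rose 2.59-fold (from 8.99 ± 0.53 to 10.36 ± 0.39 log2 CPM, adjusted p = 0.0119), and Lipc, hepatic lipase, fell to 72.6% of WT (adjusted p = 0.0372), while 18 of 23 apolipoprotein and lipoprotein genes were lower (camera adjusted p = 0.00375, 0.448 with an estimated correlation). Of the drug metabolism genes under CAR and PXR, 11 of 15 were lower and 2 fell, Cyp2c29 to 54.4% of WT (adjusted p = 0.0357) and Ugt1a1 to 65.1%, the latter named after its value was seen (camera 0.00511, 0.477 with an estimated correlation). Cyp2c37 fell to 50.7% of WT (adjusted p = 0.0144) among 20 pericentral hepatocyte genes, of which 2 fell. Of 20 periportal genes 2 rose and 2 fell, Serpina1c, a serine protease inhibitor, to 68.4% (adjusted p = 0.0282). Mup20, a major urinary protein, rose 2.29-fold among 23 male-biased genes (adjusted p = 0.00772) and Ntrk2, a neurotrophin receptor, 3.15-fold among 8 measured female-biased genes (adjusted p = 0.0365). Mcm6, a subunit of the replicative helicase, rose 1.90-fold among 22 cell cycle genes (adjusted p = 0.0372). Cyp2c, Serpina1 and Mup genes have near-identical copies, so their levels are uncertain where reads are shared. Adjusted over the list alone, 2 lipoprotein genes rose and 6 fell, 0 drug metabolism genes rose and 4 fell, and 1 pericentral gene rose and 4 fell. In the periportal, male-biased, female-biased and cell cycle lists 3, 5, 1 and 2 genes rose and 3, 2, 2 and 1 fell. The calls of Lipc, Cyp2c29, Serpina1c, Ntrk2 and Mcm6 were lost without 9, 9, 9, 6 and 9 of the single libraries, with adjusted p of up to 0.0878, 0.0817, 0.0672, 0.0902 and 0.0920.

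By limma 0 genes were called in the lists of p53 targets, endoplasmic reticulum stress, ATF4 targets, cytosolic ribosomal proteins, acute phase proteins, interferon-stimulated genes, growth hormone and insulin signalling, mitochondrially encoded genes or immediate early genes. The members closest to the threshold were Ccng1 (adjusted p = 0.121), Pdia6 (0.395), Nupr1 (0.0985), Rps7 (0.171), Hamp2 (0.171), Bst2 (0.0902), Akt2 (0.355), mt-Nd6 (0.232) and Klf6 (0.0728). Camera adjusted p of these 9 lists were 0.0712, 0.553, 0.443, 0.120, 0.956, 0.529, 0.473, 0.0143 and 0.443, and that of the mitochondrially encoded genes was 0.602 with an estimated correlation and up to 0.196 without WT 6, DKO 4 or DKO 5. Adjusted over the list alone, 1 immediate early gene rose and 0 genes of the other 8 lists were called. Camera adjusted p were 0.120 for the pericentral, 0.930 for the periportal, 0.138 for the male-biased, 0.916 for the female-biased and 0.0620 for the cell cycle list. Median and mean log2 fold change had opposite signs for periportal genes (-0.02 and 0.09), acute phase proteins (-0.03 and 0.13) and female-biased genes (0.02 and -0.09), with camera's direction down for the first and up for the other two.

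Several lists and genes that did not pass did so with 1 library left out. By camera these were cytosolic ribosomal proteins, whose adjusted p spanned 0.000495 to 0.964 and was below 0.05 without WT 1, WT 5 or DKO 3, and p53 targets without WT 1, DKO 5 or DKO 6 (lowest 0.0374). The cell cycle list passed without WT 1, WT 2, DKO 5 or DKO 6 (lowest 0.0192), red blood cells without WT 2, DKO 3, DKO 4 or DKO 6 (0.0269), the pericentral list without WT 1 or DKO 6 (0.0195) and the male-biased list without WT 1 or DKO 2 (0.0123). Endoplasmic reticulum stress (0.0141) and neutrophils (0.0491) passed without WT 1. Among genes, limma's adjusted p was below 0.05 for Klf6 without WT 1 (0.0371), Bst2 without DKO 2 (0.0448) and Lpcat3, Cdh5 and Cd74 without DKO 6 (0.0460, 0.0489 and 0.0404). In the exact permutation test of the mean level, adjusted over the 40 lists, PPARα targets (0.0289), the clock, extracellular matrix, endothelial, p53 and other acetyl-CoA lists (0.0481 each) passed without WT 1. Without DKO 2 the other acetyl-CoA list passed (0.0289), and without DKO 6 the endothelial (0.0289) and hepatocyte identity (0.0346) lists.

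By camera with its preset correlation 19 of the 40 lists differed between the groups (7 higher and 12 lower in DKO), by fry 12, by the exact permutation test of the mean level 3, and by camera with an estimated correlation 0 (smallest adjusted p = 0.20). The 3 lists of the exact test, mitochondrial fatty acid oxidation, macrophages and monocytes, and NRF2 targets and glutathione, were called by camera and fry too. Among the 1000 most variable genes the first principal component held 21.3% of the variance and separated the groups in part (exact permutation p = 0.0108).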

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

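In this part, the test on a swap of labels and the fit without both libraries numbered 1 were chosen after the results were seen. In 12 of the 218 combinations of a group and a result, the gap between the most extreme library and the next exceeded Dixon's 95% limit for 6 libraries, where chance gives about 1 in 20, or 10.9; each gap is given last as a fraction of the group's range. WT 1 was high for Acss2 (7.45 log2 CPM, the other 5 at 6.12 to 6.50; 0.711) and the mean level of ATF4 targets (3.51 against 2.39 to 2.76; 0.672). It was low for Ppara (6.77 against 7.36 to 7.59; 0.718) and Adam11 (5.95 against 6.66 to 7.08; 0.626). DKO 1 was high on the first principal component (42.2 against 3.43 to 12.1; 0.776). WT 5 was low for Lpcat3 (6.69 against 6.88 to 6.99; 0.635) and high for hepatocyte identity (10.30 against 10.03 to 10.13; 0.646). DKO 2 was high for Acaa1b (10.37 against 9.36 to 9.74; 0.626) and the LXR targets (6.05 against 5.602 to 5.74; 0.697), and low for Plin3 (5.33 against 5.72 to 5.86; 0.736). DKO 6 was high for hepatocyte identity (10.16 against 9.92 to 9.96; 0.824) and low for endothelial cells (4.64 against 4.85 to 4.98; 0.629).

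The 2 libraries numbered 1 stood apart in the same direction: each had the highest Acly, Acss2 and cholesterol synthesis level of its group and the lowest PPARα target level, and 5 of the 12 extreme values were theirs. A swap of their labels was excluded, since Acly was 2.75 log2 CPM higher in WT 1 than in DKO 1. For a more recent meal in these mice, the mean level of fasting-induced genes had a summed rank of 8. This explanation needed 4 or less, and 8 fell within the bound set in advance against it. But the level lay within 1 SD of the group mean in both libraries (7.35 against 7.04 ± 0.42 and 7.12 against 7.03 ± 0.31 log2 CPM). Both libraries also had the highest fatty acid synthesis level and the lowest Cpt1a of their groups, measures outside that rule. A more recent meal therefore cannot be told apart. A shared time of day or day of collection cannot be told apart: the deviations of 17 clock genes in WT 1 and DKO 1 correlated at r = 0.765 across genes, which are not independent, but the highest of the other 35 pairs reached 0.767. The labels give no day or time of collection, no biological explanation beyond the meal and the time of day was tested, and without both libraries 255 genes were called, 161 of them among the 214.

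For the whole comparison, 100 ways to split the 12 libraries into 6 and 6 were drawn, the real one included. Only the real split (1 of 100) called as many as 214 genes, the highest other calling 1. Chance is therefore unlikely to give that number of genes, though 100 of the 462 possible splits were drawn. For the camera calls on lists, 7 of the 100 splits gave as many as the 19 of the real one, the highest other 26, so chance is not excluded for the number of lists called that way.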

How the results depend on the processing

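Leaving out both libraries numbered 1, the exact permutation test over all lists and the permutation of replicate numbers were chosen after seeing the data; the other alternatives were planned. Of the 214 called genes 0 turned direction in the limma fits, which tested 197 of them at a mean of at least 1 log2 CPM and 163 at a mean of at least 3, and Acly and Acss2 stayed called in each limma fit (log2 fold change of Acly -2.81 to -2.16 and of Acss2 -2.47 to -1.997 with 1 library left out). With 1 library left out, 92 to 373 genes were called, 34 to 156 higher and 58 to 217 lower, and 38 to 119 at least 2-fold, 23 to 78 higher and 15 to 41 lower. Camera's adjusted p then ranged over 0.0269 to 0.238 for polyunsaturated fatty acid synthesis, 0.00354 to 0.0575 for lipid droplets, 2.46e-06 to 0.0814 for cholesterol synthesis and 0.193 to 0.882 for fatty acid synthesis. The lowest count, 92, was without WT 5 and the highest, 373, without WT 1. Of the 19 lists called by camera 14 stayed called in all these fits. Without both libraries numbered 1, 255 genes were called (96 higher, 159 lower), 161 of them among the 214. What depth limits is unknown, since the table carries no counts.

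Without the mean trend 138 genes were called (76 lower), and 11 named genes lost and 1, Nupr1, gained a call. On log2(CPM + 1) 28 genes were at least 2-fold higher. At a mean of at least 3 log2 CPM, where 8026 genes remained, 46 were higher and 30 changed at least 2-fold (14 higher, 16 lower), and camera's adjusted p was 0.0425 for polyunsaturated fatty acid synthesis, 0.0521 for lipid droplets, 0.0283 for ribosomal proteins and 0.0436 for red blood cells. The cell cycle list passed on log2(CPM + 1) (0.0478) and with medians subtracted (0.0393). With quantile normalization 109 genes were called (48 higher, 61 lower, 26 at least 2-fold higher), with p of 0.0115 for polyunsaturated fatty acid synthesis, 0.0766 for lipid droplets and 0.1996 for other acetyl-CoA enzymes. It also ended the calls of bile acid (0.412), lipoprotein (0.339), hepatocyte identity (0.336) and mitochondrially encoded genes (0.1996) and of 14 named genes, among them Pcx, Ccr2 and Hsd17b4, while ribosomal proteins (4.30e-08) and male-biased genes (0.0142) passed. Array weights called 356 genes (145 higher, 211 lower), among them Ebp, Lpcat3 and Mlxipl, and the ribosomal list passed (0.00350), as it did without both libraries numbered 1 (0.000475). Exact rank-sum tests called 0 genes, 0 higher and 0 lower (1742 at an unadjusted p below 0.05): 266 genes had the smallest p possible, where a call needed 532. For the other alternatives the cause was not tested.

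With the replicate number as a block 397 genes were called (136 higher, 261 lower, 43 at least 2-fold lower), with p of 0.00421 for polyunsaturated fatty acid synthesis; Lpcat3, Cd74, Klf6, Srebf1 and Mlxipl gained a call, Plin3 and Sparc lost theirs, and no other call of a named gene or list changed. Same-numbered libraries correlated at r = 0.29, -0.08, 0.09, 0.0957, 0.20 and 0.04 in their deviations, 2 of 6 above 0.1. Of the 12 libraries 7 correlated best with their own number. The mean r of 0.106 lay in the upper tail of the 720 orders of the DKO numbers, whose mean was 0.00053 (exact permutation p = 0.00833, one-sided). These values point to a link between same-numbered libraries. The numbers were not taken to pair the samples because the labels do not say that they do. This hint comes from the data, not the design, and the labels give no meaning to the numbers.

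The exact permutation test called 3 lists, with adjusted p of 0.326 for cholesterol synthesis, 0.0866 for PPARα targets and extracellular matrix, 0.181 for lipid droplets and 0.0649 for other acetyl-CoA enzymes. Estimated correlations called 0 lists, with p of 0.620 for cholesterol synthesis, 0.398 for lipid droplets, 0.241 for extracellular matrix and 0.20 for mitochondrial oxidation, PPARα targets, other acetyl-CoA enzymes and macrophages. Fry called 12, with 0.390 for cholesterol synthesis and 0.153 for lipid droplets. Camera could not be run with robust limma.

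Log2 fold changes turned sign with medians subtracted (Cpt1a -0.00604, Cd36 -0.011), array weights (Fasn -0.19, Cd36 -0.00627) and both libraries numbered 1 left out (Cpt1a -0.0610, Cd36 -0.0924), and with 1 library left out spanned -0.23 to 0.63 for Fasn, -0.11 to 0.12 for Cpt1a and -0.15 to 0.18 for Cd36. Lists that turned direction had adjusted p of 0.993 (acute phase, no trend), 0.987 (periportal), 0.647 (ATF4) and 0.647 (female-biased) at a mean of at least 1, and 0.743 (periportal), 0.930 (cholangiocyte), 0.545 (ATF4) and 0.997 (interferon) at a mean of at least 3. With quantile normalization they were fatty acid synthesis (0.930), LXR targets (0.959), periportal (0.138), female-biased (0.925) and growth hormone genes (0.925). Others were endoplasmic reticulum stress (0.749) and female-biased genes (0.993) with array weights, female-biased genes (0.979) with the block and periportal genes (0.894) without both libraries numbered 1. In the exact test they were fatty acid synthesis (0.921), periportal (0.479), female-biased (0.875) and pancreas and adipose genes (0.139). With 1 library left out, p spanned 0.409 to 0.996 for periportal, 0.0141 to 0.937 for endoplasmic reticulum stress, 0.123 to 0.997 for acute phase, 0.123 to 0.964 for interferon and 0.571 to 0.996 for female-biased genes. Fatty acid synthesis, with p of 0.193 to 0.882, turned direction without WT 1. As CPM relative to WT, the log2 ratio of the pancreas and adipose level in DKO to that in WT was 0.268.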

Other observations

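The tests on macrophage, oxidation and Gstm genes, and the gene families, were chosen after the results they concern were seen; the test on lysosomal genes was chosen before. A list of 18 genes of lipid-associated macrophages was higher in DKO (8 rose, 0 fell; median log2 fold change 0.96, camera p = 1.59e-15, and p = 0.00291 with an estimated correlation), while in a list of 14 resident Kupffer cell genes 0 were called by limma (median 0.39, camera p = 6.30e-06, and p = 0.0273 with an estimated correlation). The mean level of the resident genes was still 0.48 higher in DKO on the log2 scale (exact permutation p = 0.00649, up to 0.0152 with 1 library left out). Of each list 7 members also stand in a fixed list. Beyond Gpnmb, Spp1 and Mmp12, the lipid-associated genes that rose included Anxa5, a phospholipid-binding protein, by 0.88 on the log2 scale (limma adjusted p = 0.000306), Cd63, a lysosomal tetraspanin, by 1.24 (0.00397), Lgals3, galectin 3, by 1.13 (0.0144), and Capg, an actin-capping protein, by 1.31 (0.0144). Trem2, the receptor that marks these cells, had 0.86 (SE 0.30), which did not pass (adjusted p = 0.158). Of 209 families of genes with a shared symbol stem, that of Hsd, named for hydroxysteroid dehydrogenases, had the smallest p by camera with its preset correlation. In it 5 of 13 fell, 0 rose, the median was -0.40, camera's adjusted p was 6.27e-05 and 0.192 with an estimated correlation. Those that fell included Hsd17b12 and Hsd17b4, so the family in part repeats results of the fixed lists. With an estimated correlation the Cyp2d family came first (camera adjusted p = 0.153). In the Ces family of carboxylesterases 3 of 14 fell, among them Ces2e by 1.09 on the log2 scale (adjusted p = 0.000827), and 3 of 11 Hist genes, which encode histones, rose. The Hist genes that rose included Hist2h2aa1 and Hist2h2aa2, close paralogs that may share reads. With an estimated correlation the Ces and Hist families had an adjusted p above 0.05 (0.571 and 0.559).

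The mean level of macrophage genes was higher and that of fatty acid oxidation genes lower in DKO, which a lower share of hepatocytes in the DKO tissue could produce. It would raise other cell types alike, but the difference in macrophage level was 0.75 larger on the log2 scale than that in the mean of endothelial, stellate and cholangiocyte levels (exact permutation p = 0.00216). These 3 levels differed by 0.23, 0.20 and 0.03, against 0.90 for macrophages, whose list holds Gpnmb, with 3 libraries at the lowest value. Lists left out of that mean differed by 0.61 (neutrophils), 0.36 (dendritic cells), 0.31 (red cells) and 0.16 (lymphocytes) and were not compared. The excess therefore holds against those 3 types only. A lower share of hepatocytes would lower oxidation and hepatocyte identity genes alike, but the mitochondrial oxidation level was lower by 0.19 more (exact permutation p = 0.0173, up to 0.0368 with 1 library left out), whereas for PPARα targets this cannot be told apart, since a difference of -0.77 (exact permutation p = 0.0498) had p of up to 0.106 with 1 library left out. A candidate explanation that stays open is a larger gain of lipid-associated macrophages than of resident Kupffer cells: with 3 and 1 genes named earlier left out, the difference in mean level was 0.32 larger for the lipid-associated genes (15) than for the resident ones (13; exact permutation p = 0.00433, up to 0.0130 with 1 library left out). With those named genes kept in, the difference in mean level was 0.62 larger. Whether macrophages were more numerous or expressed more of these genes, or other liver cells did, was not tested. An effect of the genotype on oxidation genes within hepatocytes stays open, untested.

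Gstm1, Gstm2 and Gstm3 rose together, and reads of 1 of them could have been assigned to the others. For Gstm1 and Gstm2 this cannot be told apart from a change of each gene. Gstm3 rose 6.64-fold (from 25.9 to 171 CPM), more than Gstm1 or Gstm2 did. A fixed share of reads from either would raise Gstm3 no more than its source rose. That argues against such sharing as the whole rise of Gstm3, provided the share was alike in both groups, which was not tested. Gstm1 gained 776 CPM (from 732 to 1508), 4.53 times the 171 CPM recorded for Gstm3 in DKO, but reads taken from Gstm3 would be missing from that value, so the ratio does not decide.

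A rise of lysosomal genes as a programme was tested on a list of 32 measured genes outside the fixed lists. Their mean level was 6.46 ± 0.04 log2 CPM in WT and 6.53 ± 0.04 in DKO (exact permutation p = 0.0130, up to 0.0281 with 1 library left out; camera p = 0.0268, and p = 0.0803 with an estimated correlation), a small difference of 0.08. Whether it is a programme or none cannot be told apart: the p-values met the bound set in advance for a programme, but the difference was also below the 0.1 set in advance as too small, by less than its spread. By limma 0 of the 32 genes were called.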
